A study of Rattus norvegicus with 12 samples.

How the data were processed

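Right lungs of 12 rats were profiled on Affymetrix rat expression arrays, with 3 arrays in each of 4 groups. Per the labels' protocols, the lung circulation was flushed with saline, the right lung was frozen, RNA was extracted with Trizol and 6 µg of total RNA was labelled with biotin; animals weighed 250 to 350 g. Groups and strain come from the labels. Separate animal numbers are given for the arrays of a group, and p-values measure the spread between these samples. No batch is stated, the groups share no replicate numbers, and the labels name 3 arrays per strain and condition.

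Values were deposited as linear intensity per probe set, and the submitters' processing notes name MAS5, whose version and settings are not given in the sources used here. The mean of the values between the 2nd and 98th percentile was 150 on each array, and the median intensity was 58.5 to 68.1, so the deposited values were taken as scaled per array and were not normalized again. Detection calls were not used here, so the distance from background is unknown for single values. Arrays give no counts, and their number limits the precision.

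Of 31099 probe sets, 57 were control probe sets and were left out of tests. A platform annotation named 1 gene for 20832 probe sets, several for 436 and none for 9780, with 14218 distinct genes; a RefSeq table of the rat assembly GRCr8 updated 0 symbols, did not hold 68 of the gene identifiers, and was used only for names and for which genes neighbour each other. Genes were never named from a probe set with several. Intensities were transformed as log2(intensity + 16), and probe sets with a mean at or above the 40th percentile, an intensity of about 42.2, were kept, which left 18625 probe sets and 10554 genes. A gene was represented by its kept probe set with the highest mean. Because 3 arrays per group give few degrees of freedom, the 4 group means were fitted in 1 model over the 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend; 8 residual degrees of freedom), and p-values were adjusted by Benjamini-Hochberg over all kept probe sets, separately for each of 6 comparisons, at a threshold of 0.05. SE are limma's moderated standard errors.

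The choices of test, filter, gene lists, alternatives and rule for named genes were made before the data were examined. The rule names, among genes past the test whose arrays did not overlap, the 8 with the largest rise and the 8 with the largest fall for HTV in each strain and for the strains in control lungs, and 5 each way in the other comparisons; it allows up to 4 members of each list with the smallest p, and a panel of genes known from lung ventilation. Among the genes it allows, the selection printed was made after the values were seen.

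The 34 lists are cytokines and chemokines, NF-kB feedback and adhesion, immediate-early genes, stretch and YAP targets, coagulation and fibrinolysis, heat shock and chaperones, Nrf2 and metallothionein, endoplasmic reticulum stress, glucocorticoid targets, circadian clock, hypoxia and glycolysis, oxidative phosphorylation, interferon response, MHC class II, cell cycle, extracellular matrix, junctions and water or ion transport, renin-angiotensin and vascular tone, and markers of 16 cell types or tissues. Of 540 entries 68 had no probe set with a single gene name and were not analysed here. List counts cover only members with a kept probe set, and the filter's mean includes the HTV arrays. A member dim in control lungs was more likely kept if HTV raised it, which favours rising members in such lists. With at least 4 measured genes required, 32 lists were tested with camera in limma (preset correlation 0.01) in 4 comparisons, and the 128 p-values were adjusted together; 36 passed, and 0 passed with an estimated correlation, where the camera test found 12 unadjusted p-values below 0.05. Members past the test were counted over all probe sets and adjusted over the list alone.

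Alternatives were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, median centring, eBayes without a trend, array weights, a block for animal numbers, only the arrays compared, the mean over a gene's probe sets, an estimated correlation, and each array left out in turn. Alternatives added after the data were seen were the beta-actin ratio as a covariate and leaving out SS control 3 and BN HTV 3 together. Permutation tests of array quality were exact and two-sided. The model was tested on simulated data with 100 probe sets changed by 0.5 and 100 by 1 log2 unit in SS HTV arrays. The simulated noise was independent between probe sets and alike for all arrays. The model recovered 18% and 89% in the SS comparison, with 7 false calls.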

Results

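The data are gene expression profiles of the right lung of rats from a pair of inbred strains, the Dahl salt-sensitive rat (SS), a model of salt-induced hypertension, and the Brown Norway rat (BN), which the labels call parents. Lungs came from control animals and from animals ventilated in a mode the labels abbreviate as HTV and do not spell out. Each of the 4 groups had 3 arrays, 12 in all. Each array measured 31099 probe sets, and 18625 of them, bright enough over the 12 arrays, were tested. The comparisons ask what HTV changed in each strain, whether the change differed between strains, and how the strains differed without and with HTV. Differences are on the log2(intensity + 16) scale with their standard error (SE), which understates changes of dim probe sets. Every group has n = 3, and the number of arrays limits the precision.

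Arrays correlated at r = 0.883 to 0.980 across the tested probe sets, and the leading principal components took 35.8%, 24.6% and 10.6% of the variance. The 5-prime to 3-prime signal ratio of the beta-actin control probe sets, a measure of RNA integrity, was -0.71 ± 0.44 in log2 (SD, n = 6) in SS arrays and -1.18 ± 0.23 (n = 6) in BN arrays. The strains differed in it by 0.47 (two-sided exact permutation test, p = 0.0498), whereas HTV and control arrays differed by -0.07 (exact permutation test, p = 0.784). The same ratio of the GAPDH control probe sets differed by 0.22 between strains and by -0.02 between HTV and control arrays (exact permutation tests, p = 0.0736 and 0.864). The lowest beta-actin ratio among the SS arrays, -1.41, belonged to SS control 3.

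SS control 3 stood apart across all tested probe sets, at 39.0 on principal component 3 against -12.9 to 14.3 in the other arrays. Its mean correlation with its own group, 0.950, and its array weight, 0.29, were the lowest. It also differed from the other SS arrays at genes that separate the strains. At 38 probe sets, every one of the other 5 SS arrays lay more than 1.5 log2 units from every BN array. SS control 3 lay past the midpoint towards the BN mean at 14 of them and below 0.25 of the way from the SS mean at 18. The major histocompatibility gene RT1-CE5 had an intensity of 498.4 in SS control 3, against a mean of 1.2 in the other SS arrays and 854.1 in BN arrays. Clec3b, which encodes tetranectin, had 198.4 against 5.2 and 421.2. Aox1, an aldehyde oxidase, had 38.1 in SS control 3, where the other SS arrays averaged 255.2 and BN arrays 48.2. In contrast, the array matched its strain at Echdc2 (372.2 against 237.3 in other SS and 15.2 in BN arrays) and at Ccn1 (8.4 against 22.0 and 372.4). In the same count for each of the other 11 arrays, 1 of 47 probe sets lay past the midpoint in SS HTV 1 and 0 in the others. These probe sets and the limits were chosen after the data were seen, and the array was kept in all comparisons as labelled.

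**Figure D1:**
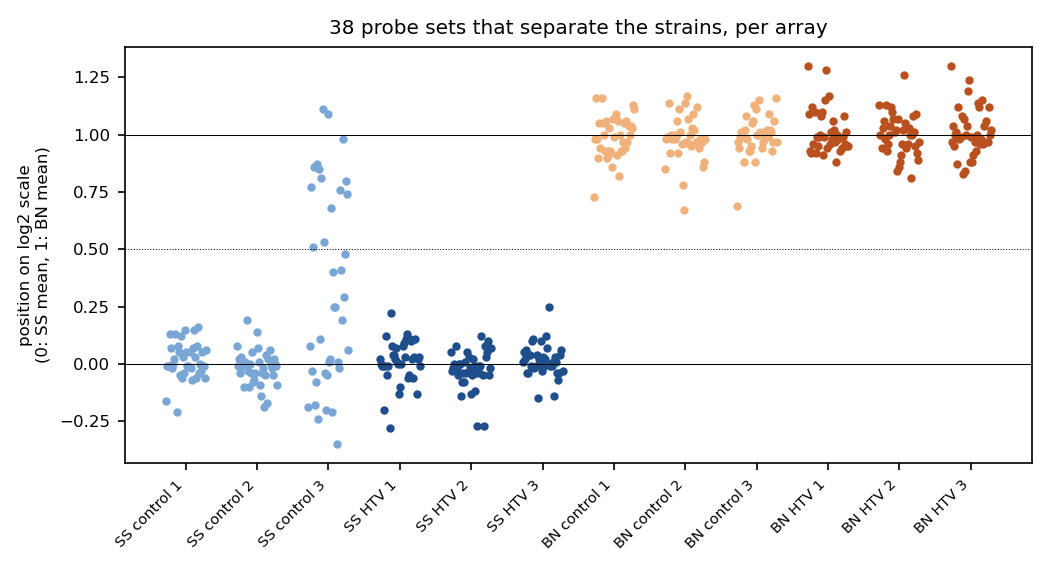
Position of each array (x axis) between the mean of the other 5 SS arrays (0) and the BN mean (1) on the log2 scale (y axis) at 38 probe sets that separate the strains; each dot is a probe set, shifted sideways at random. SS control 3 lies past the midpoint at 14 of the 38 and below 0.25 at 18, while the other SS arrays lie near 0 and the BN arrays near 1.

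HTV raised inflammatory and early-response genes in SS lungs. The interleukin Il1a rose by 3.14 ± 0.17 (adjusted p = 8.41e-07), from an intensity of 124 ± 10.3 to 1238 ± 264 (SD, n = 3). The neutrophil-attracting chemokine Cxcl2 rose by 3.13 ± 0.58 (adjusted p = 0.00553), and the metalloproteinases Mmp9 and Mmp8 rose by 3.58 ± 0.74 and 2.80 ± 0.48. The cysteine protease inhibitor Stfa2l2 rose by 2.76, Depp1 by 2.72, the metallothionein Mt2A by 2.63 and Lrrc32, a surface anchor of latent transforming growth factor beta, by 2.57. Among falling genes were regulators of the endothelium, with Sox18 at -1.71 ± 0.29 (adjusted p = 0.00316), the flow-responsive factor Klf2 at -1.46 and the Notch target Hey1 at -1.46, together with Id3, a target of bone morphogenetic protein signalling, at -1.62 ± 0.16 (adjusted p = 0.000104). Ighvl1, an immunoglobulin heavy chain gene, fell by 1.49, Btbd3 by 1.47, S100pbp by 1.33 and Rbm12b by 1.28.

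In SS lungs 19 of 26 measured immediate-early genes rose and 1 fell (22 and 1 adjusted over the list alone). Egr1 rose by 2.54, Atf3 by 2.45, Nr4a1 by 2.25 and Fos by 1.33. The gene that fell was Klf2. The list shifted upwards by a mean of 0.98 (camera, adjusted p = 1.62e-16 with the preset correlation; adjusted p = 0.166 with an estimated correlation). Of 14 cytokines and chemokines 7 rose and 7 did not pass (9 adjusted over the list alone), with Cxcl1 at 1.81 and Osm at 1.81 (list adjusted p = 5.77e-05; adjusted p = 0.486 with an estimated correlation). Il1b at 1.49 ± 0.59 did not pass (adjusted p = 0.137). Of 17 NF-kB feedback and adhesion genes 6 rose and 11 did not pass (10 adjusted over the list alone), among them Tnfaip3 at 2.27 and Nfkbia at 1.22 (list adjusted p = 7e-07; adjusted p = 0.486 with an estimated correlation). SS HTV 2 stood apart in these lists, with a mean of -0.02 for cytokines and chemokines against 0.92 and 0.83 in SS HTV 1 and 3, and of -0.15 for NF-kB feedback and adhesion against 0.66 and 0.80. Of 14 glucocorticoid targets 8 rose and 6 did not pass (12 adjusted over the list alone), with Cdkn1a at 2.18, Errfi1 at 1.74 and Cebpd at 1.62 (list adjusted p = 3.23e-10; adjusted p = 0.166 with an estimated correlation). Of 6 neutrophil markers 4 rose and 2 did not pass (6 adjusted over the list alone), including Il1r2 at 2.44 and S100a8 at 2.16 (list adjusted p = 1.78e-05; adjusted p = 0.486 with an estimated correlation).

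Of 14 coagulation and fibrinolysis genes in SS lungs 4 rose and 10 did not pass (5 higher and 1 lower adjusted over the list alone), with tissue factor, F3, at 1.45, Plaur at 1.27 and Plat at 1.15 (list adjusted p = 0.00874; adjusted p = 0.486 with an estimated correlation). In the Nrf2 and metallothionein list 4 of 10 rose (4 adjusted over the list alone), with Srxn1 at 1.27 (list adjusted p = 0.0129; adjusted p = 0.486 with an estimated correlation). In the hypoxia and glycolysis list 4 of 14 rose (4 adjusted over the list alone), with Pfkfb3 at 1.45 and Ndrg1 at 0.62 (list adjusted p = 0.0107; adjusted p = 0.486 with an estimated correlation). Of 14 T and NK cell markers 4 fell and 10 did not pass (6 adjusted over the list alone), with the granzyme Gzma at -1.19 ± 0.14 and Klrb1a at -0.94 (list adjusted p = 0.00874; adjusted p = 0.635 with an estimated correlation). The list's mean was -0.01 in SS control 3, as in the SS HTV arrays (-0.03 to 0.05), against 0.59 and 0.58 in the other SS controls, and without SS control 3 the shift went from -0.38 to -0.57. Of 18 interferon response genes 4 rose, 1 fell and 13 did not pass (4 and 1 adjusted over the list alone), with Ifit3 at 1.42, Oasl at 1.22 and Ifit2 at 0.92 (list adjusted p = 0.00252; adjusted p = 0.635 with an estimated correlation). The mean of this list was -0.27 in SS control 3 and 0.23 and 0.48 in the other SS controls, and without SS control 3 the shift was 0.24 (adjusted p = 0.0801). In the renin-angiotensin and vascular tone list 3 of 11 rose (3 adjusted over the list alone), with endothelin, Edn1, at 1.18 (list adjusted p = 0.042; adjusted p = 0.573 with an estimated correlation). Of 5 red cell and platelet genes the platelet gene Pf4 rose by 1.25 (2 adjusted over the list alone; list adjusted p = 0.0146; adjusted p = 0.486 with an estimated correlation). The cardiac muscle list shifted upwards by 0.73 with 0 of 11 genes past the limma test or adjusted over the list alone, 2 of them at an unadjusted p below 0.05, among them Tnnc1 at 1.20 (list adjusted p = 0.0432; adjusted p = 0.83 with an estimated correlation).

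The surfactant gene Sftpc (0.04 ± 0.14), the club cell gene Scgb1a1 (-0.03 ± 0.14), Nos3 (0.21 ± 0.19), Mylk (0.05 ± 0.10), Ace (0.11 ± 0.12), Hmox1 (-0.13 ± 0.63) and Ccl2 (-0.13 ± 0.77) did not pass in SS lungs. In all, 1502 probe sets passed, 728 higher and 774 lower, with 222 higher and 69 lower by at least 2-fold. Of the probe sets, 4711 had an unadjusted p below 0.05 where chance gives 931. Arrays of the groups did not overlap for 3241 of 10554 genes, where chance gives 10%. The count fell to 904 without SS control 2, 992 without SS control 3, 630 without SS HTV 1, 681 without SS HTV 3 and 810 with the 6 SS arrays alone. Median centring moved the share of higher calls from 48.5% to 36.2%. Of the 54 calls named for this comparison 51 were kept whichever array was left out. Those of Mmp9 (adjusted p = 0.0577) and Pf4 (adjusted p = 0.058) were lost without SS HTV 1, and that of Hey1 without any of 5 SS arrays (adjusted p = 0.0567 to 0.102). Leaving out 1 array also ended the list calls of T and NK cells (SS control 1, adjusted p = 0.0921) and of red cells and platelets (SS control 2, adjusted p = 0.106). The renin-angiotensin list's call was lost without SS control 1, SS control 3, SS HTV 2 or BN HTV 2 (adjusted p up to 0.156), and the cardiac list's without SS control 2, SS HTV 1, SS HTV 2 or BN HTV 1 (adjusted p up to 0.379). Other processing also ended them. The renin-angiotensin call was lost without a filter (0.0637), with the 60th percentile filter (0.0991), quantile normalization (0.0539), array weights (0.0808) and the mean of probe sets (0.1), and the cardiac call with a pseudocount of 64 (0.0828), without a filter (0.0636), with the 60th percentile filter (0.145) and with quantile normalization (0.0793). The interferon call was lost with array weights (0.0888). The cardiac shift was 0.44 without SS control 2, 0.30 without SS HTV 1 and 1.24 without SS HTV 3, and the red cell and platelet shift went from 0.80 to 0.50 without SS control 2. Among further probe sets of these genes, 1 of Ndrg1 did not pass (0.32, adjusted p = 0.388), nor did 1 of Klf2 (-0.33, adjusted p = 0.293).

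**Figure D2:**
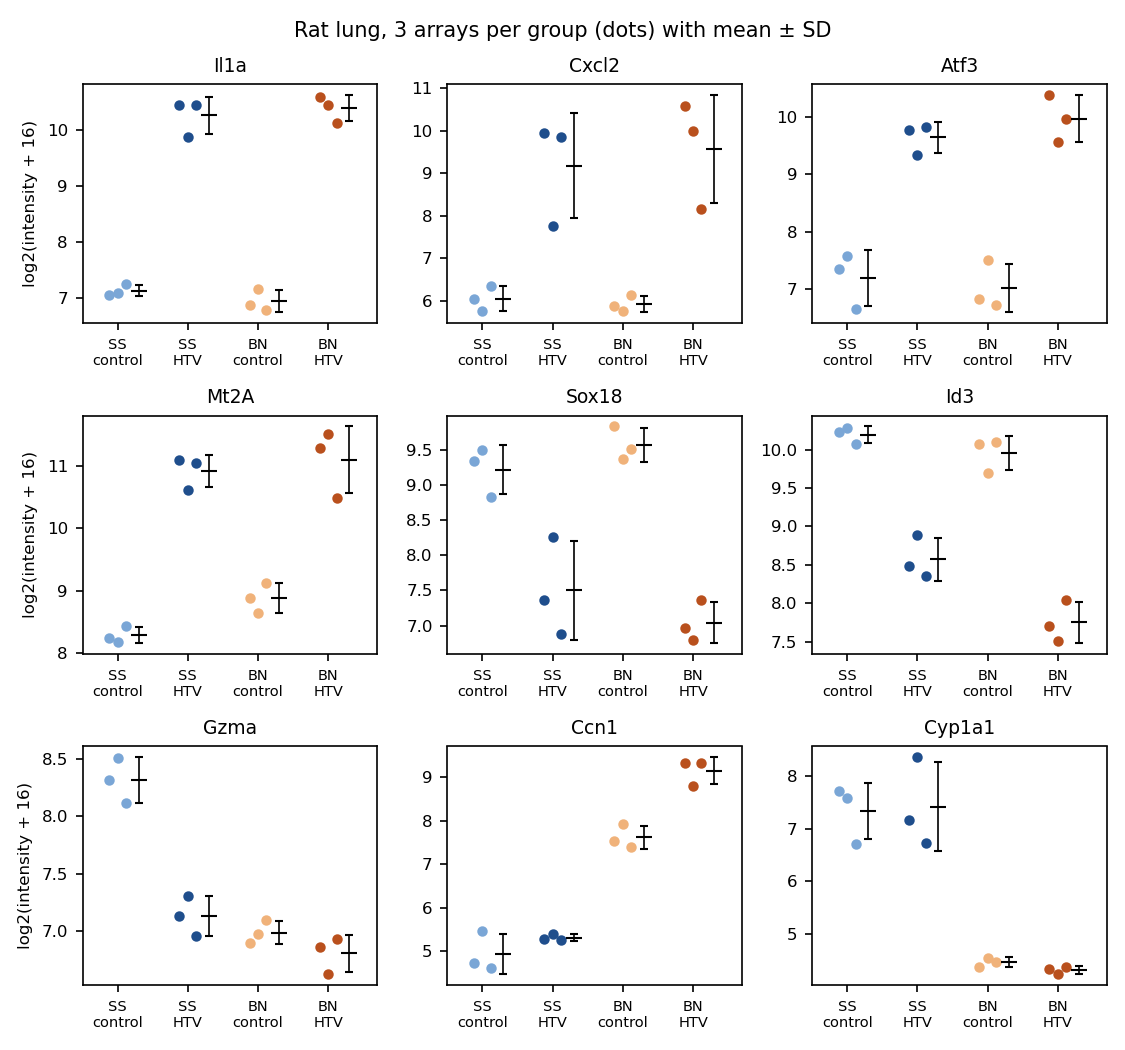
Expression of 9 genes as log2(intensity + 16) on the y axis of each panel in SS control, SS HTV, BN control and BN HTV lungs; dots are the 3 arrays of a group and bars the mean ± SD. Il1a rose by 3.14 in SS and 3.46 in BN lungs, Sox18 fell by 1.71 and 2.52, and Ccn1 was lower and Cyp1a1 higher in SS than in BN lungs in both conditions.

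In BN lungs Cxcl2 rose by 3.65 ± 0.58 (adjusted p = 0.00251) and Il1a by 3.46 ± 0.17 (adjusted p = 2.39e-07), the latter from 107 ± 17.1 to 1344 ± 212 (SD, n = 3). Stfa2l2 rose by 3.24, Tmem252 by 2.97, the stress-induced transcription factor Atf3 by 2.96 ± 0.27, Mmp9 by 2.82, the decoy interleukin receptor Il1r2 by 2.74 and S100a8, a calcium-binding protein of neutrophils, by 2.71. Sox18 fell by 2.52 ± 0.29 (adjusted p = 0.000234) and Id3 by 2.21 ± 0.16 (adjusted p = 1.19e-05). Hey1 fell by 1.57, the homeobox gene Hoxa5 by 1.46, the Wnt target Axin2 by 1.38, the nuclear receptor coactivator Ncoa3 by 1.37, Ap5z1 by 1.33 and Klf2 by 1.23.

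Of the 26 immediate-early genes 21 rose and 1 fell in BN lungs (22 and 1 adjusted over the list alone), with Nr4a1 at 2.18 and Fos at 1.94. The gene that fell was Klf2, and the list shifted by a mean of 1.10 (list adjusted p = 5.73e-24; adjusted p = 0.166 with an estimated correlation). Of 14 cytokines and chemokines 6 rose (9 higher and 1 lower adjusted over the list alone), with Cxcl1 at 1.83 and Osm at 1.77 (list adjusted p = 7.87e-09; adjusted p = 0.358 with an estimated correlation). Il1b at 1.92 ± 0.59 did not pass (adjusted p = 0.0785). Of 17 NF-kB feedback and adhesion genes 4 rose (8 adjusted over the list alone), with Tnfaip3 at 2.32, Ptgs2 at 1.77 and Nfkbia at 1.21 (list adjusted p = 3.61e-08; adjusted p = 0.486 with an estimated correlation). Of 14 glucocorticoid targets 8 rose (8 adjusted over the list alone), with Cebpd at 1.83, Errfi1 at 1.62 and Cdkn1a at 1.52 (list adjusted p = 1.15e-11; adjusted p = 0.166 with an estimated correlation). Of 6 neutrophil markers 5 rose (6 adjusted over the list alone), with S100a9 at 2.16 (list adjusted p = 5.34e-08; adjusted p = 0.358 with an estimated correlation); the list's mean was 1.60 and 1.16 in BN HTV 1 and 2 and -0.19 in BN HTV 3. BN HTV 3 also stood apart for cytokines and chemokines (0.08 against 1.29 and 1.14) and for NF-kB feedback and adhesion (-0.11 against 0.90 and 0.68).

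The coagulation and fibrinolysis list had 4 higher and 2 lower of 14 (6 and 2 adjusted over the list alone), with F3 at 1.67 and Plat at 1.12 (list adjusted p = 0.00321; adjusted p = 0.486 with an estimated correlation). In the stretch and YAP targets, genes induced by mechanical load, 3 of 13 rose and 1 fell (4 and 1 adjusted over the list alone), with Areg at 1.63, Ccn1 at 1.54 and Edn1 at 0.94 (list adjusted p = 0.0367; adjusted p = 0.358 with an estimated correlation). The Nrf2 and metallothionein list had 4 of 10 higher (4 adjusted over the list alone), with Mt2A at 2.21 and Srxn1 at 0.82 (list adjusted p = 0.000631; adjusted p = 0.358 with an estimated correlation). The hypoxia and glycolysis list had 2 of 14 higher (3 higher and 1 lower adjusted over the list alone), with Pfkfb3 at 1.72 (list adjusted p = 0.00468; adjusted p = 0.466 with an estimated correlation). In the endoplasmic reticulum stress list 3 of 15 rose (3 adjusted over the list alone), with Herpud1 at 0.84 and Trib3 at 0.69 (list adjusted p = 0.0115; adjusted p = 0.635 with an estimated correlation). In the cell cycle list 1 of 14 rose (1 adjusted over the list alone; list adjusted p = 0.0051; adjusted p = 0.635 with an estimated correlation). BN HTV 2 stood apart in both lists, with a mean of 0.35 for endoplasmic reticulum stress against 0.03 and 0.06, and of 0.60 for the cell cycle against 0.03 and -0.05. Without it the shifts went from 0.18 to 0.07 and from 0.28 to 0.08, and that of the Nrf2 and metallothionein list from 0.46 to 0.30. Without BN control 3 the endoplasmic reticulum stress shift was 0.27. Of 14 T and NK cell markers 1 fell (3 adjusted over the list alone; mean -0.35, list adjusted p = 0.0051; adjusted p = 0.635 with an estimated correlation). The red cell and platelet list shifted by 0.80 with 0 of 5 genes past the limma test and 2 adjusted over the list alone (2 at an unadjusted p below 0.05; list adjusted p = 0.0107; adjusted p = 0.486 with an estimated correlation).

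Sftpc (-0.01 ± 0.14), Scgb1a1 (0.03 ± 0.14), Nos3 (0.13 ± 0.19), Mylk (-0.16 ± 0.10), Ace (-0.14 ± 0.12), Hmox1 (0.46 ± 0.63) and Ccl2 (0.79 ± 0.77) did not pass in BN lungs. The test called 1084 probe sets, 552 higher and 532 lower, with 193 higher and 56 lower by at least 2-fold. Of the probe sets, 3712 had an unadjusted p below 0.05. Arrays of the groups did not overlap for 2804 of 10554 genes, where chance gives 10%. The count fell to 580, 573 and 619 without BN control 1, 2 and 3, and to 540 and 560 without BN HTV 1 and 2, and rose to 1658 with array weights. Median centring moved the share of higher calls from 50.9% to 60.8%. Of the 46 calls named for this comparison 41 were kept whichever array was left out. Those of Mmp9 (adjusted p up to 0.161), Hey1 (up to 0.0965), Klf2 (up to 0.0778), Nampt (up to 0.182) and Timp1 (up to 0.115) were lost without at least 1 array. So were the list calls of stretch and YAP targets (up to 0.0646), endoplasmic reticulum stress (up to 0.227), cell cycle (0.249 without BN HTV 2) and T and NK cells (0.0738 without BN HTV 2). The stretch and YAP call was also lost with the 60th percentile filter, where the shift went from 0.41 to 0.17 (list adjusted p = 0.541), with quantile normalization (0.11) and with a pseudocount of 1 (0.0503). The endoplasmic reticulum stress call was lost with array weights (0.129). Further probe sets that did not pass were 1 each of Pfkfb3 (0.45, adjusted p = 0.305), Mmp9 (1.88, adjusted p = 0.0575) and Klf2 (-0.28, adjusted p = 0.47).

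**Figure D3:**
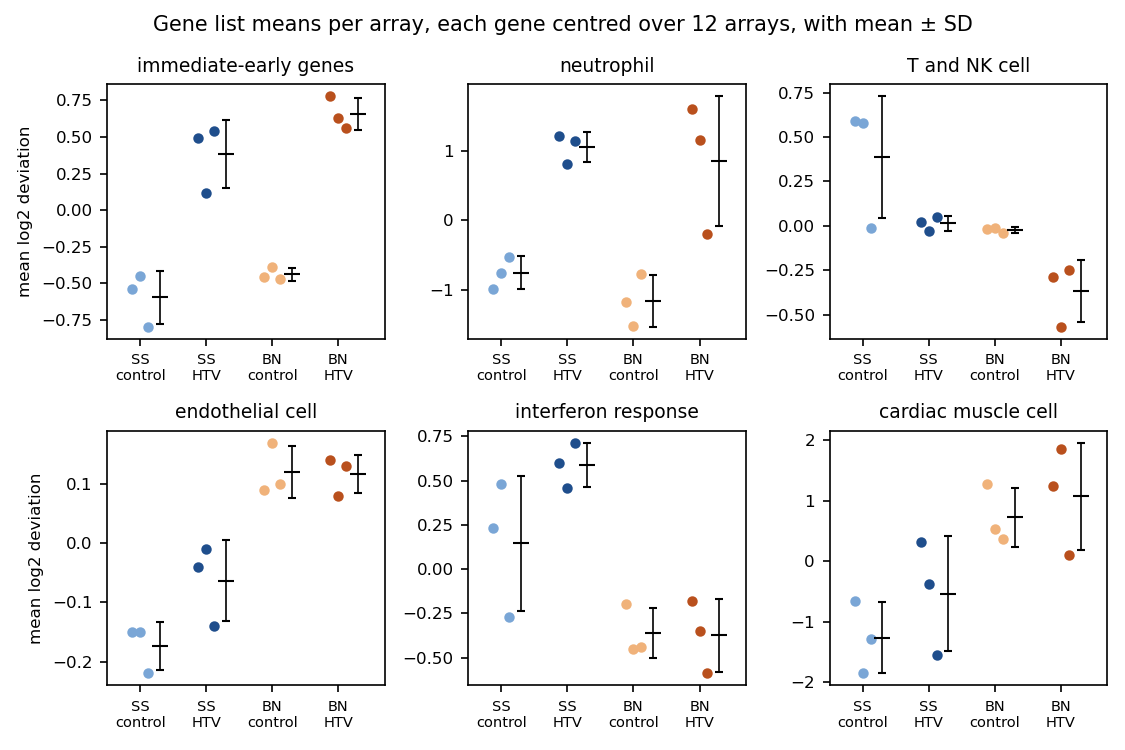
Mean log2 deviation of 6 gene lists (y axis), each gene centred over the 12 arrays, in SS control, SS HTV, BN control and BN HTV lungs; dots are arrays and bars the mean ± SD over 3 arrays. The neutrophil mean lies at 0.81 to 1.22 in SS HTV and at -0.99 to -0.52 in SS control lungs, and the cardiac muscle mean is lower in SS than in BN control lungs.

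The remaining lists did not pass in either strain under HTV, and some passed in 1 strain only. In the strain where they did not pass, the shifts were 0.23 for stretch and YAP targets, 0.02 for endoplasmic reticulum stress and 0.12 for the cell cycle in SS lungs, and -0.01 for the interferon response, 0.10 for renin-angiotensin and vascular tone and 0.35 for cardiac muscle in BN lungs. Ccn1, a member of the stretch list, lay at an intensity of 28.2 or below in every SS array. It could hardly add to the SS shift, so the strains are not compared on equal terms for this list. In SS lungs the growth factor gene Areg rose by 1.32 and Chac1 by 0.60, and Amotl2 fell by 0.61. The cardiac shift in BN lungs passed without BN HTV 3 (0.83, list adjusted p = 0.00317) and without BN control 1 (0.63, list adjusted p = 0.0213). The extracellular matrix list shifted by 0.29 and 0.06. In BN lungs the mean and the direction of the camera test differed in sign for the extracellular matrix, interferon, oxidative phosphorylation and type 2 cell lists, none of which passed. With HTV in SS and in BN lungs the mean shifts were -0.16 and -0.08 for heat shock and chaperones, -0.10 and -0.01 for oxidative phosphorylation, 0.14 and -0.03 for MHC class II, and 0.07 and 0.10 for junctions and water or ion transport. The clock list shifted by 0.34 in both, with 3 of 15 genes higher in each, among them Nfil3 (1.85 and 1.51) and Bhlhe40 (1.37 and 1.59) and, in BN lungs, Per1 (1.60), 1 lower in SS lungs, and a list adjusted p of 0.143 and 0.0512. In SS lungs it was 0.00578 without SS control 3 and 0.0239 with array weights. In BN lungs it was 0.0217 without BN control 1, 0.0492 with a pseudocount of 1, 0.0363 with array weights, 0.0343 with a block for animal numbers and 0.0267 with the mean of probe sets, and it also passed without any 1 of SS control 2, SS control 3, BN control 2, SS HTV 1, SS HTV 3 and BN HTV 2 (up to 0.0493). Among cell type markers the shifts were -0.14 and -0.04 for type 2 and -0.15 and -0.14 for type 1 alveolar cells, 0.18 and 0.09 for club and ciliated cells, 0.11 and 0.00 for endothelial cells, and 0.11 and 0.18 for smooth muscle. They were -0.13 and -0.18 for fibroblasts, 0.27 and 0.08 for macrophages and monocytes, -0.10 and -0.46 for B and plasma cells, -0.13 and -0.45 for mast cells, and 0.13 and 0.00 for mesothelial cells. Further lists passed under other settings. In BN lungs B and plasma cells passed without a filter (-0.57, list adjusted p = 0.006), with median centring (-0.43, 0.0437), without BN control 1 (-0.50, 0.0431) and without BN HTV 1 (-0.60, 0.00901), and fibroblasts without BN control 2 (-0.29, 0.0151). Smooth muscle in BN lungs passed without BN control 3 (0.26, 0.00988), BN HTV 3 (0.25, 0.0204) or SS control 3 (0.18, 0.0487) and with the beta-actin ratio as a covariate (0.21, 0.0352). In SS lungs the extracellular matrix list passed without SS control 3 (0.28, 0.0264) or SS HTV 3 (0.32, 0.0457), the cell cycle without SS control 3 (0.23, 0.0446) and oxidative phosphorylation without SS control 1 (-0.16, 0.0355). Single genes past the test in these lists included the macrophage lipopolysaccharide receptor Cd14 (1.14), the chaperone regulator Bag3 (0.61) and the fibroblast factor Tcf21 (-0.78) in SS lungs. The thymus and adipocyte lists had under 4 measured genes and were not tested.

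The difference of the HTV effect between strains was tested directly, since the strains are described as parents and a difference in response would separate them. No gene passed. The difference, SS minus BN, was -1.16 ± 0.32 for Ccn1 and 0.98 ± 0.21 for Col1a1 (adjusted p = 0.528 for both). It was -0.98 ± 0.40 for the protease inhibitor Timp1 (adjusted p = 0.577) and -0.61 ± 0.19 for Fos (adjusted p = 0.557). Ccn1 lay at an intensity of 28.2 or below in every SS array, under the filter's intensity of about 42.2, so an HTV effect in SS lungs could hardly be seen. Timp1 rose in BN lungs (1.17) and not past the test in SS lungs (0.19), and Nampt likewise (0.70 and 0.41), but neither difference passed (adjusted p = 0.763 for Nampt). Cxcl2 differed by -0.52 ± 0.81 and Il1r2 by -0.30 ± 0.67.

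By list, the interferon response shifted upwards in SS relative to BN lungs by 0.45 with 0 of 18 genes past the limma test or adjusted over the list alone, and 5 of 18 at an unadjusted p below 0.05 (list adjusted p = 0.000344; adjusted p = 0.573 with an estimated correlation). Without SS control 3 this shift was 0.25 (adjusted p = 0.0204), and with array weights 0.21 (adjusted p = 0.0808). Ifit3 had an HTV effect of 1.42 in SS and 0.67 in BN lungs, and Ifit2 of 0.92 and 0.39. The extracellular matrix list shifted by 0.23, with 0 of 23 genes past the limma test, 1 adjusted over the list alone and 9 at an unadjusted p below 0.05 (list adjusted p = 0.0336; adjusted p = 0.532 with an estimated correlation). Its call was lost without any of 5 arrays, which were SS control 1, BN control 1, BN control 3, SS HTV 2 and BN HTV 1 (adjusted p = 0.0723 to 0.161). Lists that had not passed did so under other settings. Among those of the inflammatory response these were immediate-early genes, with a shift of -0.12, without SS control 3, SS HTV 1, SS HTV 3 or BN HTV 3 (-0.22 to -0.16, list adjusted p = 0.00369 to 0.0494) and with array weights (-0.25, list adjusted p = 0.00178), and neutrophil markers, with -0.20, without BN HTV 3 (-0.73, list adjusted p = 0.00149). Without BN HTV 3 the shift of cytokines and chemokines went from -0.25 to -0.63 (list adjusted p = 0.0025) and that of NF-kB feedback and adhesion from -0.04 to -0.34 (list adjusted p = 0.0484), and cytokines and chemokines also passed without SS HTV 1 (-0.42). Endoplasmic reticulum stress, at -0.15 (list adjusted p = 0.0736), passed without a filter or without any 1 of SS control 2, BN control 3, SS HTV 1, BN HTV 1 and BN HTV 3 (-0.24 to -0.15, smallest list adjusted p = 0.00245). T and NK cells passed without SS control 3 (-0.22, 0.0108) and with array weights (-0.21, 0.0303), the cell cycle without BN HTV 3 (-0.28, 0.0221) or SS HTV 3 (-0.24, 0.0443), and endothelial cells with quantile normalization (0.18, 0.0126) or without SS HTV 3 (0.15, 0.0443). Oxidative phosphorylation passed without SS control 1, BN control 1 or BN HTV 3 (-0.16 to -0.14, adjusted p = 0.0232 to 0.0411), and renin-angiotensin and vascular tone without SS control 2, SS HTV 1 or BN HTV 3 (0.21 to 0.23, adjusted p = 0.0272 to 0.0498). Leaving out 1 array also brought past the test B and plasma cells (BN HTV 1, 0.50, 0.0255), mast cells (SS control 3, 0.42, 0.0487), cardiac muscle (SS HTV 3, 0.89, 0.0113) and type 2 cells (SS HTV 1, -0.18, 0.0323). Stretch and YAP targets (-0.29, 0.0225) and smooth muscle (-0.24, 0.0107) passed only without SS control 3 and BN HTV 3 together. In limma 0 of 18625 probe sets passed (smallest adjusted p = 0.528), although 1551 had an unadjusted p below 0.05 where chance gives 931. In simulated data, 3% of probe sets changed by 0.5 and 25% of those changed by 1 log2 unit in SS lungs alone were recovered in this test. The simulated noise was independent between probe sets and alike for all arrays. The real arrays differed in quality (array weights 0.29 to 1.97), so these shares are only a rough guide. Without SS control 2 the test called 1 probe set.

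Of the 728 and 552 probe sets higher in SS and BN lungs, 341 were shared, where independent lists would share 21.6, and of the 774 and 532 lower, 250 were shared, where independent lists would share 22.1. None (0) passed in opposite directions. Across the 18625 probe sets, which are not independent replicates, the effects correlated at r = 0.636. The compared groups share no arrays.

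**Figure D4:**
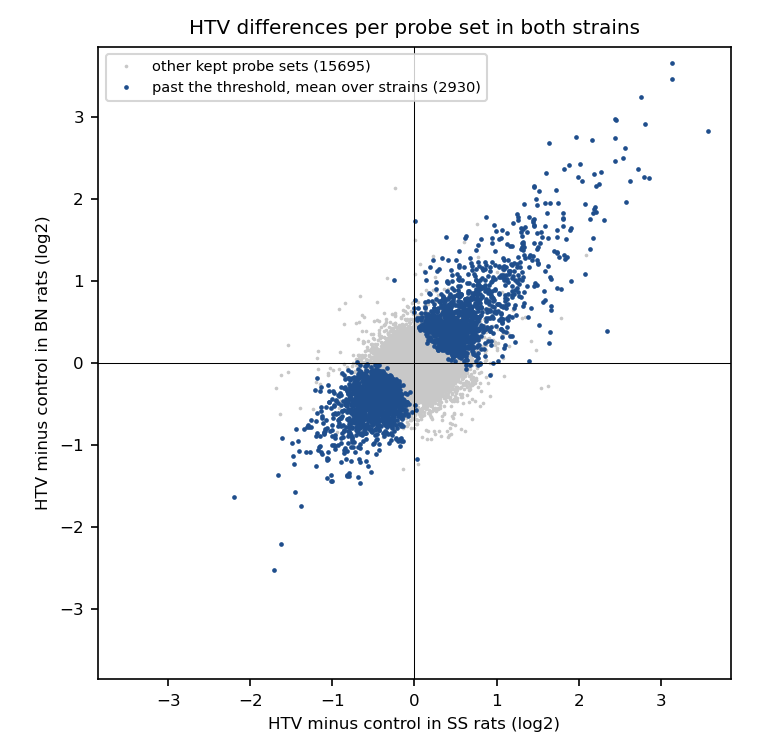
HTV effect in SS (x axis) and BN lungs (y axis) as log2 differences for the 18625 tested probe sets; each dot is a probe set, and those past the test of the mean over strains are coloured. The effects correlate at r = 0.636 across probe sets; the 2930 coloured dots were selected on the mean over both strains, which itself favours equal signs.

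Averaged over strains, with 6 arrays against 6, HTV raised Cxcl2 by 3.39 ± 0.41 (adjusted p = 0.000109), Il1a by 3.30 ± 0.12 (adjusted p = 4.7e-09), Mmp9 by 3.20 ± 0.52, Stfa2l2 by 3.00 ± 0.37 and Tmem252 by 2.70 ± 0.20. Sox18 fell by 2.12 ± 0.20 (adjusted p = 1.72e-05), Id3 by 1.92 ± 0.12 (adjusted p = 4.42e-07), Hey1 by 1.51, Klf2 by 1.35 and Btbd3 by 1.31. Genes short of the test in the strains passed here, among them Il1b at 1.71 ± 0.42 (adjusted p = 0.0141), and Nampt had 0.56 ± 0.13. All 6 neutrophil markers with a kept probe set rose (6 adjusted over the list alone), with Mmp8 and S100a9 among them. The other markers fixed for this list were not measured, and the filter favours markers that rose. Of the immediate-early genes 23 of 26 rose and 1 fell (23 and 1 adjusted over the list alone), and 12 of 17 NF-kB feedback and adhesion genes rose (14 adjusted over the list alone), with Nfkbiz and Ptgs2 among them. Of 14 T and NK cell markers 6 fell (6 adjusted over the list alone), including Lck and the perforin gene Prf1. A dimmer probe set of Klf2 had -0.30 and did not pass (adjusted p = 0.147).

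The averaged test called 2930 probe sets, 1308 higher and 1622 lower, with 211 higher and 47 lower by at least 2-fold, and 5610 had an unadjusted p below 0.05. Arrays did not overlap in either strain for 1234 of 10554 genes, where chance gives 1%. All 21 calls named for the averaged effect were kept whichever array was left out.

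In control lungs Echdc2, a mitochondrial enoyl-CoA hydratase domain protein, was higher in SS lungs by 3.16 ± 0.30 (adjusted p = 3.5e-05), the leukocyte integrin subunit Itgal by 3.15 ± 0.20 (adjusted p = 8.6e-07; 664 ± 180 against 58.8 ± 7.1, SD, n = 3) and the cytochrome P450 gene Cyp1a1 by 2.88 ± 0.34. Stfa2l2 was higher by 2.33, the ubiquitin ligase Rnf6 by 2.23, the proteoglycan gene Ogn by 2.05, and the histocompatibility genes RT1-T24-3 and RT1-A by 1.89 and 1.85. RT1-CE5 was lower in SS lungs at -4.14 ± 0.89 (adjusted p = 0.0111), Clec3b at -3.32 ± 0.64 (adjusted p = 0.00643), Cped1 at -2.84, the matricellular stretch-responsive gene Ccn1 at -2.68 ± 0.22, the mitotic kinase Aurkb at -2.61, and the cardiac genes Tnnt2, Nppa and Myh6 at -2.61, -2.60 and -2.55. RT1 genes belong to a family of near-identical, variable copies, so their values are uncertain. SS control 3 set the spread of several (RT1-CE5 167 ± 287, RT1-T24-3 231 ± 267 and Clec3b 69.8 ± 111, SD, n = 3). Without it RT1-CE5 lay at -5.76, Clec3b at -4.43 and RT1-T24-3 at 1.03. Echdc2, Itgal, Cyp1a1, Rnf6, Ccn1 and Aurkb had no other tested probe set, so sequence variants were not told apart from differences in expression. Ccn1 lay at an intensity of 28.2 or below in every SS array, under the filter's intensity of about 42.2, so the size of its difference is uncertain. Cyp1a1 (4.9), Rnf6 (12.7) and Echdc2 (15.2) had BN means under that intensity. So did RT1-CE5 (1.2) and Clec3b (5.2) in the mean of the SS arrays other than SS control 3. The sizes of these differences are uncertain too, in control lungs and under HTV.

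Of 11 cardiac muscle markers 9 were lower in SS control lungs and 2 did not pass (11 adjusted over the list alone), with Tnnc1 at -1.98 (mean -1.99, list adjusted p = 7e-07; adjusted p = 0.486 with an estimated correlation). Of 12 endothelial markers 2 were lower, among them Vwf at -0.89 (7 adjusted over the list alone; list adjusted p = 0.00106; adjusted p = 0.229 with an estimated correlation). Of 18 interferon response genes 5 were higher in SS lungs (9 adjusted over the list alone), with Irf7 at 1.20 (list adjusted p = 0.000161; adjusted p = 0.57 with an estimated correlation). Of 23 extracellular matrix genes 7 were higher (10 adjusted over the list alone), with Col1a1 at 0.85 (list adjusted p = 0.002; adjusted p = 0.466 with an estimated correlation). Of 10 fibroblast markers, 5 of them shared with that list, 3 were higher (5 adjusted over the list alone; list adjusted p = 0.00753; adjusted p = 0.486 with an estimated correlation). Of 14 T and NK cell markers 4 were higher (4 adjusted over the list alone), with Gzma at 1.33 ± 0.14 (list adjusted p = 0.0086; adjusted p = 0.635 with an estimated correlation), and the list's mean in SS control 3, -0.01, lay in the range of the BN controls (-0.04 to -0.01). Of 9 macrophage and monocyte markers 4 were higher, with the complement gene C1qc at 1.07 (5 higher and 2 lower adjusted over the list alone; list adjusted p = 0.0411; adjusted p = 0.57 with an estimated correlation). Of 21 oxidative phosphorylation genes 3 were higher (3 adjusted over the list alone; list adjusted p = 0.00334; adjusted p = 0.645 with an estimated correlation). Outside these lists, the coagulation gene Fgl2 was higher by 1.04, and Srxn1 at -0.71 and the anchoring protein gene Akap5 at -1.57 were lower. The strains also differed in the beta-actin ratio by 0.47, and with it as a covariate the T and NK cell and macrophage lists did not pass (adjusted p = 0.0674 and 0.122).

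The strain test in control lungs called 2281 probe sets, 1088 higher and 1193 lower in SS, with 113 higher and 264 lower by at least 2-fold. Of the probe sets, 5390 had an unadjusted p below 0.05, and arrays did not overlap for 3440 of 10554 genes, where chance gives 10%. Of 276 genes past the test with another tested probe set, the other had the same sign in 221 (80.1%, 95% exact binomial interval 74.9 to 84.6%). For genes called for HTV this share was 91% in SS and 87.6% in BN lungs. The count was 1127 without SS control 2, 744 without BN control 2, 1330 without BN control 3, 1463 with the 6 control arrays alone and 4090 with array weights. Median centring moved the share of higher calls from 47.7% to 68%. Of 25 calls named for this comparison 20 were kept whichever array was left out. Those of Stfa2l2 (up to adjusted p = 0.0575), RT1-T24-3 (up to 0.113), Tnnt2 (up to 0.0695), Nppa (up to 0.136) and Myh6 (up to 0.129) were lost without at least 1 control array. So were the T and NK cell list (SS control 1, 0.0921) and the macrophage list (up to 0.148), which was also lost with median centring (0.0613). The interferon shift went from 0.51 to 0.34 without SS control 2, the macrophage shift from 0.26 to 0.14 without BN control 2, and the oxidative phosphorylation shift from 0.20 to 0.13 without SS control 3 or BN control 2. With a block for animal numbers the calls of RT1-T24-3, Nppa and Myh6 were lost, and the smooth muscle list passed (0.27, list adjusted p = 0.039), as it did without SS control 3 (0.29, 0.0383). MHC class II also passed without SS control 3 (0.37, 0.0191), red cells and platelets without SS control 2 (0.79, 0.0405) and B and plasma cells with median centring (-0.27, 0.0479). Further probe sets that did not pass were 1 each of Ogn (0.68, adjusted p = 0.219), Col1a1 (0.33, adjusted p = 0.109) and Fgl2 (0.34, adjusted p = 0.159).

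Under HTV the probe sets called between strains in control lungs had the same sign for 95% of those higher and 90.9% of those lower in SS lungs, while 389 of 1088 and 504 of 1193 passed again. Itgal was higher in SS lungs by 3.41 ± 0.20 (adjusted p = 3.48e-07), Echdc2 by 3.25 ± 0.30, Cyp1a1 by 3.12 ± 0.34, Ogn by 2.71 and Rnf6 by 2.21. RT1-CE5 was lower at -5.53 ± 0.89 (adjusted p = 0.00213), Clec3b at -4.21, Ccn1 at -3.84 ± 0.22 (adjusted p = 3.48e-07), the skeletal actin gene Acta1 at -2.73 and Aurkb at -2.71. Of 18 interferon response genes 11 were higher in SS HTV lungs (13 adjusted over the list alone), with Ifit3 at 1.83, Isg15 at 1.73, Irf7 at 1.72 and Ifi27 at 0.92. Of 23 extracellular matrix genes 8 were higher (10 higher and 1 lower adjusted over the list alone), with Col1a1 at 1.83 ± 0.15 and Fbn1 at 0.90. Of 9 macrophage markers 4 were higher (5 adjusted over the list alone), with C1qb at 1.11 and C1qc at 1.01. Of 11 cardiac muscle markers 3 were lower (10 adjusted over the list alone). Of 12 endothelial markers 2 were lower, Vwf at -0.59 and Pecam1 at -0.63 (2 adjusted over the list alone). Edn1 was higher by 0.96 and Cdkn1a by 1.14, and Akap5 at -1.95 and Trib3 at -0.70 were lower. Further probe sets of named genes that did not pass were those of Trib3 (-0.14 and -0.22, adjusted p = 0.682 and 0.464), some of Ogn (0.24 and 0.57, adjusted p = 0.745 and 0.0983) and 1 of Fbn1 (0.35, adjusted p = 0.0753).

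The strain test under HTV called 1535 probe sets, 711 higher and 824 lower in SS, with 153 higher and 247 lower by at least 2-fold. Of the probe sets, 4346 had an unadjusted p below 0.05, and arrays did not overlap for 2982 of 10554 genes, where chance gives 10%. The control and HTV comparisons, which share no arrays, would share 41.5 higher and 52.8 lower probe sets if independent, and 1 passed in opposite directions. They also use a common estimate of the spread per probe set, which by itself makes calls coincide more often. The count fell to 684 without SS HTV 2, 762 without SS HTV 3, 984 without BN HTV 1, 888 without BN HTV 2 and 587 with the beta-actin ratio as a covariate. All 24 calls named here were kept whichever array was left out, and a second probe set of a called gene had the same sign in 135 of 188 genes (71.8%, 95% exact binomial interval 64.8 to 78.1%).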

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

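The tests of array SS control 3 against a mixture and against RNA integrity were chosen only after the result was seen, as was leaving out SS control 3 and BN HTV 3 together. The difference of the HTV effect between strains was itself tested for 32 lists, and 2 lists differed with the preset correlation. The interferon response list had a difference of 0.45, SS minus BN (list adjusted p = 0.000344), and the extracellular matrix list one of 0.23 (list adjusted p = 0.0336). With an estimated correlation neither passed. Among 43 genes and 32 lists, 0 genes and 0 lists moved in opposite directions on every array without a test of the difference.

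The interferon difference rests in part on array SS control 3, whose list mean of -0.27 lay below those of the other SS controls (0.23 and 0.48). Without that array the difference was 0.25 (list adjusted p = 0.0204), with array weights 0.21 (list adjusted p = 0.0808), and without SS control 3 and BN HTV 3 together 0.14 (list adjusted p = 0.261). What set that array apart could therefore also enlarge the interferon difference.

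SS control 3 lay past the midpoint towards BN lungs at 14 of 38 probe sets that separate the strains and below 0.25 at 18. The array also stood apart across all tested probe sets (39.0 on principal component 3, against -12.9 to 14.3), which the tests on markers do not address. A mixture with BN RNA would move every marker brighter in BN lungs by the same part on the linear scale, but 9 of 24 such markers lay below 0.1 of the way and 10 above 0.4, and lower RNA integrity would lower signals, but 9 of these markers were more than 4-fold above the brightest other SS array, which argues against both. An animal that differs in genotype at part of the genome may be the source, and neighbouring markers would then lie on the same side: among 43 named markers with a gap above 1 log2 unit, a wider set than the 38, 13 of 24 neighbouring pairs did, where 12.5 would by chance (null SD 2.4; one-sided permutation test, 100000 resamples, p = 0.504). Near one another in the histocompatibility region, RT1-Ba lay at -0.21 and -0.02 of the way and RT1-CE5 at 0.74 to 0.87. This would go against a block of BN genotype there, but RT1 values are uncertain. Probe sets of RT1-Ba disagreed in the strain difference in control lungs (1.35 against -5.29 and -4.68), so the evidence is weak. A pair of Jund probe sets lay at -0.05 and 0.51. The markers are few, so the explanation stays open; the requirement that the count be beyond its null SD to exclude it was added after the value was seen, and by the criterion written first it would have been excluded.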

How the results depend on the processing

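The beta-actin covariate and leaving out SS control 3 and BN HTV 3 together were chosen only after the data were seen; the other alternatives were not. No paired analysis was possible because the groups share no replicate numbers. A block for animal numbers of SS rats gave 1615 probe sets for HTV in SS lungs and 1723 between strains in control lungs; 3 named calls no longer passed with it and 2 lists newly passed.

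With array weights, 1658 probe sets passed for HTV in BN lungs (1084 without weights) and 4090 between strains in control lungs (2281). With only the arrays compared, 810 passed for HTV in SS lungs (1502) and 1463 between strains in control lungs (2281), where fewer arrays estimate the spread. With the beta-actin ratio as a covariate 587 passed between strains under HTV (1535). With an estimated correlation 0 list results passed in camera instead of 36, with 12 at an unadjusted p below 0.05. Apart from the estimated correlation, which by construction allows for genes of a list varying together, and the smaller sets of arrays, the cause was not tested.

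With each of the 12 arrays left out in turn, the count ranged from 630 to 1506 for HTV in SS lungs, from 540 to 1462 for HTV in BN lungs, from 0 to 1 for the difference between strains, from 744 to 2328 between strains in control lungs and from 684 to 2200 under HTV. It ranged from 2189 to 3033 for the mean over strains and from 32 to 46 for lists. The other counts stayed within 1.5 times the reported count under the other alternatives.

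No named gene or list reversed a call. For named genes, 4626 of the alternative results kept direction and side of the threshold, 72 no longer passed, 9 newly passed, and 35 that had not passed changed sign. For the other probe sets of named genes these numbers were 45, 16, 0 and 3. For lists, 2843 kept both, 88 no longer passed, 78 newly passed and 179 that had not passed changed sign. Without detection calls, the signal over background of single values is unknown, which limits statements on dim probe sets.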

Other observations

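The tests of the cardiac markers against varying amounts of cardiac muscle and against sequence variants, the list of BMP, Notch and SoxF genes and its tests against endothelial RNA and short-lived transcripts were chosen only after the result was seen.

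Each of the comparisons of 3 with 3 arrays allows 10 splits, too few for a share under 0.05. The real split was the 1 with the highest count each time, with 1502 for HTV in SS lungs (highest other 0), 1084 in BN lungs (0), 2281 between strains in control lungs (3) and 1535 under HTV (0). For the mean over strains 1 of 100 splits within strains, the real one, reached 2930, with 129 the highest other. A share of 1 in 100 is the smallest possible here, so chance is unlikely but not strictly excluded. Nor do splits address anything that ran alongside the groups. For the difference between strains all 100 splits reached the real count of 0, and the highest other, 2930, came from exchanging HTV and control in 1 strain. For lists, 41 of 100 regroupings gave at least 36 results (highest 58). Such regroupings keep the strain and HTV structure of the arrays, so their counts are not those of chance alone. The test therefore cannot decide for or against chance, which is not excluded for the lists.

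Several endothelial transcription factors fell with HTV, and 23 measured genes were gathered into a list. It holds targets, receptors, ligands and signal mediators of BMP and Notch signalling, the SoxF factors, and the further transcription factors Klf2, Hhex and Meox2. Klf2, Hhex and Meox2 fell past the test in both strains and in their mean, so the counts and list p-values do not describe these pathways alone. In SS lungs 7 fell and 2 rose (camera, p = 0.00462; p = 0.163 with an estimated correlation), in BN lungs 9 fell and 1 rose (p = 3.7e-06; p = 0.0364 with an estimated correlation), and the other members did not pass. Smad9, which transmits BMP signals, fell by 0.97 ± 0.11 in SS lungs (adjusted p = 0.000232) and by 1.01 ± 0.11 in BN lungs (adjusted p = 0.000183). Hhex fell by 1.27 and 1.08, and the homeobox gene Meox2 by 1.15 and 1.01. Sox7 fell by 0.74 in BN lungs, and the Notch target Heyl rose by 1.51 in SS lungs. Averaged over the strains, the Notch target Hey2 (-0.60) and the Notch ligand Dll4 (-0.53) were lower past the limma test (adjusted p = 0.0135 and 0.0153). Over the strains, direct targets did not pass for Id1 (-0.23), Id2 (-0.07), Smad6 (-0.14), Smad7 (-0.03) and Hes1 (-0.04), while Id4 (0.42, adjusted p = 0.00397), Heyl (0.99) and the receptor gene Notch4 (0.45) rose, although some other probe sets of Id4 did not pass. These genes lie outside the rule for named genes and were chosen after their values were seen.

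Over the strains the list shifted by -0.47, with 10 genes lower and 3 higher (camera, p = 0.000132; p = 0.0719 with an estimated correlation), which is not independent evidence since the list was drawn up from these data. A smaller share of endothelial RNA would lower endothelial markers, but their mean was 0.05 and their median -0.01. The SE of that mean, 0.11, is over 12 genes and does not measure the spread between animals. Over arrays the marker mean was -0.17 ± 0.04 in SS control and -0.06 ± 0.07 in SS HTV lungs (SD, n = 3). In BN lungs it was 0.12 ± 0.04 and 0.12 ± 0.03. These values argue against a smaller share as the source of the list's shift. Of the markers 3 rose and 1 fell past the test, so a small loss stays open. A general loss of short-lived transcripts stays open: immediate-early genes had a mean of 1.04, but HTV induced 23 of 26, which fixes that sign. For RNA integrity no difference was seen between HTV and control lungs. The beta-actin ratio differed by -0.07 and the GAPDH ratio by -0.02 (exact permutation tests, p = 0.784 and 0.864), against a beta-actin SD of 0.38 within groups. These ratios give no sign of such a cause, but a small difference stays open. As a covariate the beta-actin ratio could hardly move the list's mean (ratio 0.99), so that test cannot decide. No biological explanation was tested, and with members moving both ways the mean does not describe a fall of the pathways' targets.

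Cardiac muscle markers were lower in SS than in BN control lungs. Varying amounts of cardiac muscle in the dissected lungs may be the source: within groups the markers rose and fell together (mean pairwise residual correlation 0.81). Sequence variants acting on single probe sets would go either way, but 11 of 11 markers were lower. The list mean was -1.84 to -0.66 in SS and 0.36 to 1.28 in BN control arrays. These values argue against variants as the source of the pattern as a whole, while a part at single markers stays open. A sign test (exact p = 0.000977) cannot be relied on here, since it needs markers that vary independently, which these do not. With the beta-actin ratio as a covariate the mean strain difference kept 0.93 of its size, from -1.99 to -1.84. Its SE of 0.02 is over markers, which vary together, and does not measure the spread between animals. The ratio overlapped between the control arrays of the strains (-1.41 to -0.23 in SS, -1.47 to -0.88 in BN). The covariate could therefore move this difference little, and RNA integrity stays open. A difference between the strains in cardiac muscle of the pulmonary veins stays open, untested.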
